A study of Mus musculus with 12 samples.

How the data were processed

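RNA was taken from the livers of 12 female C57Bl/6 mice, 6 wild-type animals (WT) and 6 animals with a knockout of Ppara (Ppara KO). The mice were adults of 12 to 14 weeks, per the labels. Each mouse gave 1 Affymetrix array of the MoGene 2.0 ST design, a 1-colour array that reads each gene through several short probes summarised into a transcript cluster. The labels number the mice within each genotype, so the arrays are separate animals. The labels used here give no collection time, fasting state, litter, hybridisation date or array batch.

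The deposited values are on the log2 scale. They were made with RMA, which corrects background, normalizes between arrays and summarises probes, and with the Partek software, per the submitters' processing notes, which give no version. The deposited values of the 12 arrays had medians between 4.13 and 4.17. RMA brings the arrays to a common distribution, so a change shared by most genes would not be visible. It also compresses the differences of dim genes, whose true folds can be larger than the printed ones. The number of arrays limits the precision: the median standard error of a log2 difference was 0.0926, and the median standard deviation (SD) within a group was 0.164.

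The value table held 41345 transcript clusters. The platform annotation listed 25335 of them, 23521 with 1 gene symbol and 1814 with several, and 16010 were not listed and stay unnamed here. Symbols were looked up by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, in which 23328 clusters were found, and 0 symbols had to be updated. Clusters with 1 symbol were tested. Where a gene had several clusters, the cluster with the highest mean over the 12 arrays stood for it, which left 22180 genes. Among 1082 genes with several clusters, 146 were called, and 1 of those had another cluster called in the opposite direction. Genes that are measured only through clusters with several symbols or none were not tested as named genes, among them some well known PPARA target genes. Their clusters were only fitted and counted.

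Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per genotype and no covariate (lmFit and eBayes, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes. A gene was called higher or lower in Ppara KO at an adjusted p under 0.05, and the number changed at least 1.5-fold was counted as well. Differences are given as Ppara KO minus WT in log2 units with the limma standard error (SE). The values of Ppara were also compared with an exact 2-sided permutation test over 924 assignments.

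Lists of genes were written from textbook knowledge before the data were examined: 43 lists with 809 different genes, of which 723 were measured. They cover fatty acid and other liver metabolism, known PPARA targets, the circadian clock, sex-biased liver genes, stress and immune responses, and markers of other cell types in or beside the liver. Lists share members. A list was called shifted with camera, a limma test of whether the members of a list move against the other genes, with a preset correlation between genes of 0.01 and an adjusted p under 0.05 over the lists. Camera with an estimated correlation and fry were run as alternatives. The fry test asks whether the genes of a list move one way on balance, or, in its mixed form, whether they change in either direction. Members were also counted with p-values adjusted over the list alone.

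Genes to be named were set by a rule written before the data were examined. The rule takes Ppara, then the 12 largest rises and the 12 largest falls among called genes whose 6 values in one genotype did not overlap the 6 in the other. It leaves out predicted genes and genes with placeholder, microRNA, olfactory receptor or similar symbols. For each list it adds up to 5 members with the smallest adjusted p, and up to 3 members with the highest level among those that were not called. Where a count of 5 or fewer members is given, its members are named even outside this rule, which means after their values were seen.

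The fit was tested on simulated data of 22180 genes with 50 changed genes at each size. It recovered 26% of the genes changed 1.25-fold, 84% of those changed 1.5-fold, and 100% of those changed 2-fold and 4-fold, with 12 false calls among 167. The real arrays gave 2268 calls, so the simulation had a stricter cut-off on the unadjusted p. Its recovery of small changes therefore does not carry over directly to the real data. In 20 simulated runs without an effect, in which genes were independent, camera called a list in 0. Random splits of the real arrays, where genes are correlated, did call lists, as stated beside the list results.

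Alternatives planned before the data were examined covered the prior of the variance, array weights, renormalization, centring, filters on dim genes, the choice of cluster, the thresholds, the replicate number as a block, each animal left out, and the set test. Leaving the clock genes out of the gene counts, trimming the female-biased list, leaving out WT animals 1, 3 and 5 and every other choice of 3 WT animals, and counting for each list the random splits with as small a camera p were added after seeing the data. No coordinates are given, since the sources used here do not name the genome build of the array. The RefSeq table served only for symbols and for which genes neighbour each other.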

Results

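Gene expression was measured in the livers of 6 WT and 6 Ppara KO female mice, with 1 array per animal. Ppara encodes PPARα, a nuclear receptor that binds fatty acids and drives the transcription of genes for fatty acid oxidation in the liver. The comparison asks which liver transcripts differ when this receptor gene is disrupted. Over 22180 genes, the first principal component held 31.7% of the variance and separated the genotypes, with Ppara KO animals at 13.2 or above and WT animals at -14.3 or below.

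Livers of Ppara KO mice had far less mRNA of Cyp4a14, a fatty acid omega-hydroxylase, and of Vnn1, a pantetheinase, both classical PPARα targets. Cyp4a14 was 48.1-fold lower, with a log2 value of 10.41 ± 0.44 in WT and 4.82 ± 0.98 in Ppara KO (mean ± SD, n = 6 each), and Vnn1 was 15.0-fold lower (7.68 ± 0.30 against 3.77 ± 0.36). Of 25 genes of peroxisomal beta-oxidation and biogenesis 11 fell and 4 rose, of 21 of mitochondrial beta-oxidation 7 fell and 1 rose, and of 16 lipid droplet genes 7 fell and 1 rose, while 30 oxidative phosphorylation genes had 0 calls. The other large difference lay in the circadian clock: Dbp, a clock output transcription factor, was 11.3-fold higher (6.34 ± 0.39 against 9.83 ± 0.42), and Npas2, a partner of BMAL1, was 11.2-fold lower (7.72 ± 0.12 against 4.24 ± 0.20).

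Altogether limma called 2268 of 22180 genes (10.2%), 989 higher and 1279 lower in Ppara KO. Of these, 508 differed at least 1.5-fold, 168 higher and 340 lower, and 152 at least 2-fold, 47 higher and 105 lower. In 1443 of the 22180 genes (6.51%), 1299 of them called, the 6 values of one genotype did not overlap the 6 of the other, an arrangement that chance gives for 0.216% of genes. Treat, a limma test against a 1.2-fold change, called 329, and an adjusted p under 0.01 left 1070.

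The targeted gene itself did not separate the genotypes. Ppara had a log2 value of 7.98 ± 0.16 in WT and 8.01 ± 0.13 in Ppara KO (mean ± SD, n = 6 each), with single animals from 7.71 to 8.14 and from 7.81 to 8.16. The difference of 0.032 (95% interval -0.15 to 0.21) had an exact 2-sided permutation p of 0.712 and a limma adjusted p of 0.882. Its 1 transcript cluster summarises probes whose place relative to the disrupted part of the gene is not given in the sources used here, so a signal that persists neither checks nor contradicts the genotype labels.

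The 12 largest falls held, besides Cyp4a14, Vnn1 and Npas2, the cytochrome P450 genes Cyp3a16 (-3.80 ± 0.27, log2 difference ± SE) and Cyp4a31 (-2.43 ± 0.21), the sulfotransferase gene Sult2a1 (-3.09 ± 0.37) and A1bg (-2.91 ± 0.35), a plasma glycoprotein gene with female-biased expression. Arntl, which encodes the clock activator BMAL1 (-2.78 ± 0.26), Serpina7, the gene of thyroxine-binding globulin (-2.28 ± 0.25), and Fitm1, a lipid droplet gene (-2.15 ± 0.13, but -1.10 with the mean of its transcript clusters), fell too. The others were Slc34a2, a sodium-phosphate cotransporter gene (-2.10 ± 0.26), and Asap2, which encodes a GTPase-activating protein (-2.10 ± 0.10). Adjusted p-values of these 12 genes ran from 8.56e-12 for Npas2 to 9.89e-05 for Slc34a2. Among genes of this rank 1 predicted gene was passed over.

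Among the 12 largest rises, 7 were clock genes: Dbp, Per3, Usp2, Ciart, Wee1, Tef and Nr1d2. The other rises were Lnx1 (1.85 ± 0.10), a ubiquitin ligase gene, the small nucleolar RNA genes AF357425 (1.72 ± 0.15) and AF357355 (1.72 ± 0.21), Dsg1c (1.66 ± 0.15), a desmosomal cadherin gene, and Coq10b (1.57 ± 0.14), which encodes a coenzyme Q binding protein. The adjusted p-values of the 12 rises ran from 5.32e-09 for Usp2 to 1.07e-04 for AF357355. For these 24 genes no WT value overlapped a Ppara KO value.

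Of 38 textbook PPARA targets measured, 15 fell, 4 rose (Acot1, Acot3, Acot4 and Acadm) and 19 were not called. Adjusted over the list alone, 22 fell and 5 rose. Retsat, a retinol saturase gene, fell by 1.69 (SE 0.092), Cpt2, the inner carnitine palmitoyltransferase, by 0.90 (SE 0.074) and Acadvl, the very long chain acyl-CoA dehydrogenase, by 0.83 (SE 0.069). The decline was not shared by the whole list: Hadha, a subunit of the mitochondrial trifunctional protein, had a difference of -0.18 ± 0.071, and Cpt1a, the outer carnitine palmitoyltransferase, of 0.23 ± 0.086, and neither was called. Fabp1, a fatty acid binding protein gene, was not called either, with log2 values of 11.26 to 11.69 in WT and 11.22 to 11.62 in Ppara KO. The list as a group was shifted down by camera (adjusted p = 4.26e-09 with the preset correlation; adjusted p = 0.300 with an estimated correlation).

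**Figure D1:**
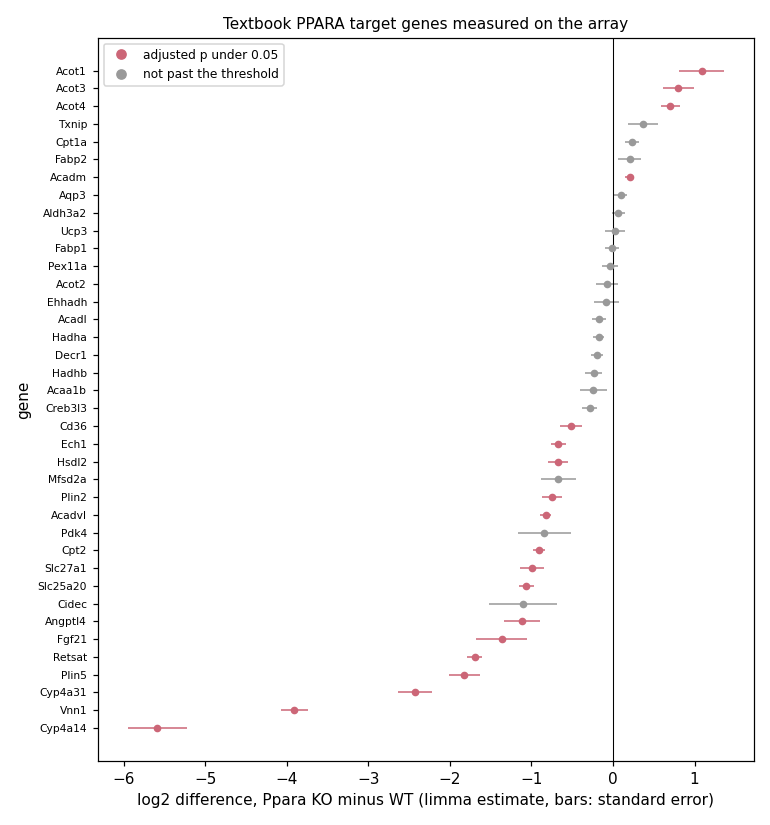
Log2 difference between Ppara KO and WT livers (horizontal axis, limma estimate with standard error bars, 6 animals per genotype) of each measured textbook PPARA target gene (vertical axis), with called genes in red. The differences run from -5.59 for Cyp4a14 to 1.09 for Acot1, and 19 of the 38 genes were called.

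In the peroxisomal list 11 of 25 genes fell and 4 rose, Acot3, Acot4, Nudt19 and Phyh (12 and 5 adjusted over the list alone). Decr2, a peroxisomal dienoyl-CoA reductase gene, fell by 1.38 (SE 0.074, adjusted p 2.22e-08), Abcd2, a peroxisomal fatty acid transporter gene, by 2.10 (SE 0.18), Hsd17b4, the D-bifunctional protein, by 0.64 (SE 0.059) and Eci2, an enoyl-CoA isomerase gene, by 0.71 (SE 0.089). Abcd2 lies 50 genes after Ppara in the gene order, among the neighbours considered further below. The camera test gave an adjusted p of 9.19e-06, and adjusted p = 0.165 with an estimated correlation. In the mitochondrial beta-oxidation list 7 of 21 genes fell and 1 rose, Acadm (9 and 2 adjusted over the list alone). The falls included Etfdh (-1.04 ± 0.068) and Etfb (-0.82 ± 0.066), which act in electron transfer from acyl-CoA dehydrogenases to the respiratory chain, and the carnitine carrier gene Slc25a20 (-1.06 ± 0.095). Its camera adjusted p was 9.30e-07, and adjusted p = 0.300 with an estimated correlation. Of 11 genes of microsomal omega-oxidation 4 fell and 0 rose, over all genes and adjusted over the list alone: Cyp4a14, Cyp4a31, Cyp4f17 (-0.77 ± 0.11) and Cyp4f15 (-0.32 ± 0.084). This list had a camera adjusted p of 0.00250, and adjusted p = 0.165 with an estimated correlation, and camera on ranks also ended the call.

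Lipid droplet genes fell as well, 7 of 16 with 1 rise (10 and 1 adjusted over the list alone). Besides Fitm1, the droplet coat genes Plin5 (-1.82 ± 0.19) and Plin2 (-0.75 ± 0.13) and Fitm2 (-0.62 ± 0.071), which acts in droplet formation, fell, while G0s2, which encodes an inhibitor of the lipase ATGL, rose (0.58 ± 0.13). The camera adjusted p was 3.12e-06, and adjusted p = 0.165 with an estimated correlation. Adipocyte markers, 2 of them also members of this list, moved the same way: 2 of 9 fell, Lipe, the hormone-sensitive lipase gene (-0.37 ± 0.088), and Adipoq, the adiponectin gene (-0.92 ± 0.26), and 0 rose. The call of Adipoq ended without any 1 of 5 animals, WT 3 and Ppara KO 1, 2, 3 and 6, and without WT 1, 3 and 5 together. Its difference ran from -1.08 to -0.39 over the alternatives. Adjusted over the list alone 6 of the 9 fell. Fabp4, the adipocyte fatty acid binding protein gene, had a difference of -1.34 ± 0.49 without a call (adjusted p 0.104), and of -0.11 without WT 1, 3 and 5. The higher WT values came from part of the animals: Fabp4 was at 7.91, 8.88 and 8.75 in WT 1, 3 and 5, but at 6.10, 5.91 and 6.14 in WT 2, 4 and 6, within the Ppara KO range of 5.52 to 6.82. The mean log2 value of the 9 markers was 5.73, 6.29 and 6.45 in WT 1, 3 and 5, 5.08, 5.09 and 5.33 in WT 2, 4 and 6, and 4.95 to 5.12 in Ppara KO. The adipocyte list had a camera adjusted p of 8.49e-04, and adjusted p = 0.334 with an estimated correlation, and the call also ended with genes at or above the median level and without WT 1, 3 and 5 (adjusted p 0.175), the only 1 of 20 choices of 3 WT animals whose removal ended it. The lipid droplet list, with a mean of 7.04, 7.24 and 7.14 in WT 1, 3 and 5, 6.78, 6.81 and 6.76 in WT 2, 4 and 6, and 6.25 to 6.52 in Ppara KO, kept its call without those 3 animals (adjusted p 9.91e-04).

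Fatty acid uptake, binding and activation had 6 falls and 3 rises, Vldlr, Acsm1 and Acsm5, among 16 genes (8 and 3 adjusted over the list alone). Fabp5, a fatty acid binding protein gene, fell by 1.23 (SE 0.12) and Slc27a1, a fatty acid transporter gene, by 1.00 (SE 0.15), while Vldlr, the VLDL receptor gene, was up 0.77 (SE 0.17). The camera adjusted p was 0.0196, and adjusted p = 0.300 with an estimated correlation, and camera on ranks and genes at or above the median level also ended the call. The adipocyte markers moved with this list, which holds Fabp4 and Lpl, in the same 3 WT animals: its mean was 8.39, 8.48 and 8.45 in WT 1, 3 and 5, 8.17, 8.13 and 8.17 in WT 2, 4 and 6, and 7.94 to 8.09 in Ppara KO. Without WT 1, 3 and 5 the call ended too (adjusted p 0.165), as it did for 4 of the 20 choices of 3 WT animals. Acyl-CoA thioesterases, which release free fatty acids from their CoA esters, went the other way: 4 of 11 rose and 0 fell (7 and 0 adjusted over the list alone). These were Acot4 (0.70 ± 0.11), Acot3 (0.80 ± 0.19), Acot7 (0.34 ± 0.086) and Acot1 (1.09 ± 0.27). The list had a camera adjusted p of 0.00599, and adjusted p = 0.334 with an estimated correlation. Acot1, Acot3 and Acot4 are neighbours in one gene family with similar sequences, and the array probes were not checked for matches to more than 1 of them.

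Circadian clock genes differed in 17 of 19 members, 13 higher and 4 lower in Ppara KO, with the same counts adjusted over the list alone. The activator side fell: Npas2 by 3.48 (SE 0.094), Arntl by 2.78 (SE 0.26) and Clock by 1.12 (SE 0.14). Genes activated through E-boxes rose, with Dbp up 3.49 (SE 0.20), the period gene Per3 up 3.04 (SE 0.16), Usp2, a deubiquitinase gene, up 2.78 (SE 0.13) and Tef, a transcription factor gene related to Dbp, up 2.21 (SE 0.11), or 1.44 with the mean of its transcript clusters. The list was shifted up by camera (adjusted p = 4.28e-08), and had adjusted p = 0.0519 with an estimated correlation. Its members moved both ways. Fry in its mixed form gave an adjusted p of 3.26e-10, but that form was run on every list and called 38 of the 43. A clock score, the mean of 11 E-box genes minus the mean of 5 genes of the BMAL1 side, was -2.33 ± 0.17 in WT and 1.45 ± 0.58 in Ppara KO (mean ± SD, n = 6 each, exact 2-sided permutation p = 0.00216, the smallest that 6 against 6 can give). The score was set up after the clock genes had been seen, so its p-value restates their separation and is no further test of it. Any difference between the genotypes in this comparison therefore lies between livers that also stood at different clock states. Leaving the clock list out gave 2245 called genes. Few genes are removed this way, so the count cannot tell whether the other calls depend on clock state.

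**Figure D2:**
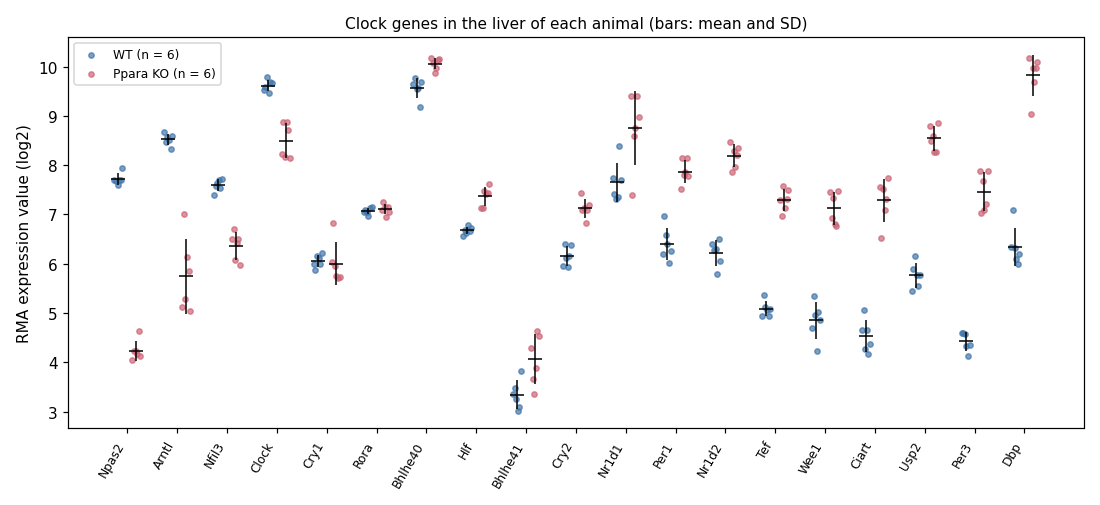
RMA expression value (vertical axis, log2) of the 19 measured circadian clock genes (horizontal axis, ordered by difference) in each WT (blue) and Ppara KO (red) liver, with black bars for the mean and SD of 6 animals. Npas2 and Arntl lie lower in each Ppara KO animal than in any WT animal, and Dbp and Per3 lie higher.

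Part of the sex-biased liver genes moved apart in these female livers. Of 23 female-biased genes 10 fell and 4 rose (Cyp2a4, Acot3, Cyp17a1 and Fmo2), with the same counts adjusted over the list alone, and of 24 male-biased genes 10 rose and 2, Elovl3 and Selenbp2, fell (12 and 2 adjusted over the list alone). The female-biased falls included Cyp4a14, Cyp3a16, A1bg, Abcd2 and Rtn4 (2.00-fold lower), and the male-biased rises included Cyp7b1, an oxysterol hydroxylase gene (1.15 ± 0.088), Mup21, a major urinary protein gene (1.48 ± 0.15), C6, a complement component gene (1.07 ± 0.12), and the organic anion transporter gene Slco1a1 (1.11 ± 0.13). Some of the female-biased genes, such as Cyp4a14 and Abcd2, are also on lists of PPARA targets or peroxisomal genes. The female-biased list had a camera adjusted p of 0.00116, and adjusted p = 0.334 with an estimated correlation, and camera on ranks also ended the call. The male-biased list had 2.00e-04, and adjusted p = 0.300 with an estimated correlation.

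Xenobiotic metabolism had 11 rises and 5 falls among 32 genes (16 and 6 adjusted over the list alone). The P450 genes Cyp2a5 (1.43 ± 0.23) and Cyp2a4 (0.86 ± 0.12) and the glucuronosyltransferase gene Ugt2b5 (0.60 ± 0.10) rose, whereas Cyp2b10, a target of the receptor CAR, fell by 1.63 (SE 0.22), as did Cyp3a16, Cyp2b9, Cyp2c70 and Gstt1. The camera adjusted p was 0.0280, and adjusted p = 0.523 with an estimated correlation. The call also ended with fry, with camera on ranks, with genes at or above the median level, without Ppara KO animal 4 or 6, and without WT 1, 3 and 5, the animals high in adipocyte markers (adjusted p 0.0532). That last loss is not particular to these animals, since 8 of the 20 choices of 3 WT animals ended the call. Among 19 bile acid genes 6 rose and 3 fell (7 and 4 adjusted over the list alone), without a shift of the list (camera adjusted p 0.0770). The transporter genes Abcc3 (0.62 ± 0.069) and Slco1a4 (0.83 ± 0.10) rose, and Hsd3b7, an enzyme gene of bile acid synthesis, fell by 0.78 (SE 0.10), as did Abcb11, the bile salt export pump gene, and Cyp8b1, a sterol hydroxylase gene.

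Cell cycle genes were lower: 13 of 28 fell and 0 rose (18 and 1 adjusted over the list alone). Top2a, a DNA topoisomerase gene, fell by 1.16 (SE 0.19), Mki67, the gene of the Ki-67 antigen, by 1.16 (SE 0.19) and Plk1, a mitotic kinase gene, by 1.15 (SE 0.19). The list had the smallest camera adjusted p, 3.52e-10, but its genes vary together between animals (correlation between genes estimated at 0.419), and adjusted p = 0.300 with an estimated correlation. In 7 of the 100 splits of the 12 arrays, the real one included, the camera p of this list was as small. The mean log2 value of the 28 genes was 5.31, 5.60 and 5.56 in WT 1, 2 and 3, 4.95, 4.97 and 4.96 in WT 4, 5 and 6, and 4.57 to 4.78 in Ppara KO, so WT 1 to 3 carried much of the difference. Camera with the preset correlation still called the list in each of 20 choices of 3 WT animals left out.

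Cholesterol synthesis had 7 falls and 0 rises among 19 genes (11 and 1 adjusted over the list alone). They included Srebf2, the gene of the transcription factor SREBP2 (-0.56 ± 0.10), and Fdps, the farnesyl diphosphate synthase gene (-0.41 ± 0.083). The camera adjusted p was 4.24e-05, and adjusted p = 0.344 with an estimated correlation. The mean of the 19 genes was 9.10 and 9.17 in Ppara KO 1 and 4, within the WT range of 9.02 to 9.23, and 8.66, 8.76, 8.85 and 8.87 in Ppara KO 2, 3, 5 and 6. In fatty acid and triglyceride synthesis 6 of 24 fell and 4 rose (9 and 4 adjusted over the list alone). The elongase gene Elovl3 fell by 1.72 (SE 0.24) and Agpat2, an acyltransferase gene, by 0.61 (SE 0.10), while Thrsp (0.93 ± 0.13), a gene induced by thyroid hormone, and Lpin1 (1.06 ± 0.21), which encodes a phosphatidate phosphatase, rose, as did Dgat2 and Lpin2, the last with the opposite sign when the transcript clusters of a gene were averaged. This list had a camera adjusted p of 0.0196, and adjusted p = 0.466 with an estimated correlation. The call also ended with fry, with genes at or above the median level, without WT animal 1 or Ppara KO animal 4 or 5, and without WT 1, 3 and 5 together (adjusted p 0.274). In all, 7 of the 20 choices of 3 WT animals ended it.

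Interferon-stimulated genes had 4 falls (Rtp4, Oasl1, Ddx60 and Mx2) and 1 rise (Bst2) among 27 (9 and 1 adjusted over the list alone), Rtp4 being at -0.33 ± 0.075 and Oasl1 at -0.45 ± 0.11. The camera adjusted p was 5.63e-04, and adjusted p = 0.334 with an estimated correlation. Of 16 immediate early genes 3 fell, Fos (-1.24 ± 0.21), Egr1 (-1.27 ± 0.28) and Btg2 (-0.77 ± 0.16), and 0 rose, also adjusted over the list alone. This list had 0.0158, and adjusted p = 0.368 with an estimated correlation, and fry, genes at or above the median level and leaving out WT 1, 3 and 5 (adjusted p 0.0835) also ended the call. In all, 7 of the 20 choices of 3 WT animals ended it.

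Of 15 endothelial markers 1 fell, the endomucin gene Emcn (-0.54 ± 0.13), and 0 rose (5 and 0 adjusted over the list alone). The camera adjusted p was 0.0105, and adjusted p = 0.490 with an estimated correlation. The mean of the 15 markers was 7.84, 7.88, 7.82 and 7.82 in WT 1, 2, 3 and 5, but 7.61 and 7.63 in WT 4 and 6, within the Ppara KO range of 7.56 to 7.74. Among 19 stellate cell and matrix genes 2 fell, Tagln (-0.49 ± 0.12) and Col4a1 (-0.34 ± 0.10), and 1 rose, Col5a2 (0.54 ± 0.11), against 5 and 1 adjusted over the list alone. Its camera adjusted p was 0.0298, and adjusted p = 0.372 with an estimated correlation. The adipocyte markers moved with it in the same animals: the mean of the 19 genes was 6.16, 6.32 and 6.32 in WT 1, 3 and 5, 6.09, 6.00 and 6.11 in WT 2, 4 and 6, and 5.96 to 6.10 in Ppara KO. Without WT 1, 3 and 5 the calls of Tagln, Col4a1 and Col5a2 ended. Over the alternatives the difference of Tagln ran from -0.57 to -0.26, that of Col4a1 from -0.40 to -0.30 and that of Col5a2 from 0.47 to 0.62. Of 21 lymphocyte and NK cell markers 3 rose, the T cell genes Cd8a (0.46 ± 0.10) and Cd8b1 (0.44 ± 0.11) and the NK receptor gene Klrd1 (0.43 ± 0.11), and 0 fell (4 and 0 adjusted over the list alone). That list had 0.0314, and adjusted p = 0.334 with an estimated correlation. The mean of its members was 4.26 to 4.37 in WT and 4.27 to 4.50 in Ppara KO, near the array medians of 4.13 to 4.17. These rises are thus small differences of dim genes. The endothelial and stellate calls also ended with fry and without WT 1, 3 and 5 (adjusted p 0.183 and 0.396), and each of the 3 with genes at or above the median level. Of the 20 choices of 3 WT animals, 4 ended the endothelial call, 10 the stellate call and 11 the lymphocyte call. The endothelial and stellate losses are therefore not particular to WT 1, 3 and 5. The stellate call ended as well without WT animal 3 or 5 or Ppara KO animal 2 or 4 and with genes at or above the 25th percentile, and the lymphocyte call without WT animal 1 or 4 or Ppara KO animal 3 or 6.

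**Figure D3:**
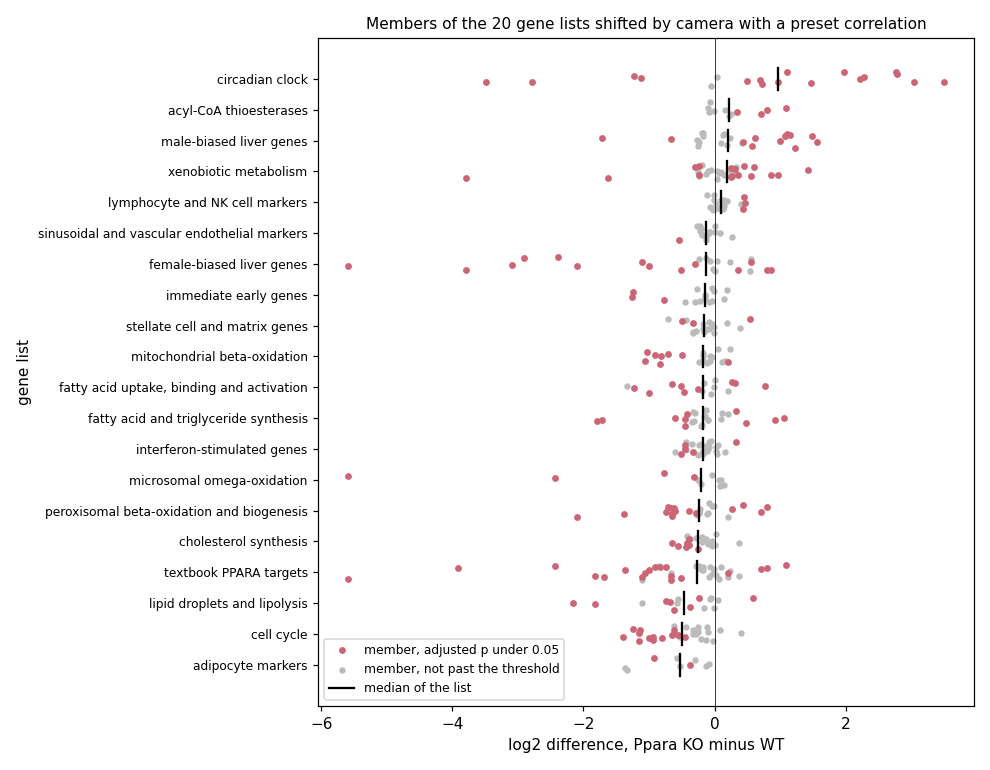
Log2 difference between Ppara KO and WT livers (horizontal axis) of each measured member of the 20 gene lists called shifted by camera with a preset correlation (vertical axis, ordered by median), with called genes in red, others in grey and the list median as a black line; the vertical spread within a list only separates points. The circadian clock list spreads from -3.48 to 3.49, and the cell cycle list has a median of -0.49.

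The remaining 23 lists were not shifted with the preset correlation, with camera adjusted p-values from 0.0531 for complement and coagulation to 0.988 for the glucocorticoid and fasting response. Complement and coagulation lay near the threshold and gained a call in 9 of 26 alternatives. Ketone body synthesis, with 3 of 5 members measured, had 1 fall, that of Slc16a1, a monocarboxylate transporter gene (-0.53 ± 0.080). Complement and coagulation had 5 rises, C6, C2 (0.62 ± 0.081), Pros1, Proc and F5, and 2 falls, Mbl1 (-0.65 ± 0.12) and C8g, among 27 genes. Lipoprotein genes had 1 rise, Apoa4, and 4 falls among 21: Pltp, the phospholipid transfer protein gene, fell by 0.81 (SE 0.12), and Angptl4, Apom and Lpl fell as well. Gluconeogenesis had 3 rises, Slc37a4, Fbp1 and Pck1, and 1 fall, that of the glucose-6-phosphatase gene G6pc (-0.61 ± 0.17), among 8 genes. Glycolysis and glucose storage had 2 rises, the glycogen synthase gene Gys2 (0.76 ± 0.13) and the glucose transporter gene Slc2a2, and 1 fall, Ppp1r3c, a glycogen-targeting phosphatase subunit gene (-0.99 ± 0.12), among 14. Amino acid catabolism had 4 rises (Oat, Tdo2, Gpt2 and Asl) and 2 falls (Bhmt and Cbs) among 30. Pericentral hepatocyte genes had 5 rises (Slc1a2, Oat, Lect2, Cyp1a2 and Cyp2e1) and 2 falls (Slc1a4 and Lgr5) among 14, and periportal genes 3 rises (Asl, Apoa4 and Pck1) and 2 falls (G6pc and Cdh1) among 13.

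The glucocorticoid and fasting response had 4 rises (Per1, Lpin1, Fkbp5 and Pck1) and 4 falls (Igfbp1, Cdkn1a, Angptl4 and Irs2) among 17 genes. Igfbp1, an insulin-like growth factor binding protein gene, fell by 1.16 (SE 0.16), and Per1, a period gene of the clock, was up 1.47 (SE 0.15). The ER stress and ATF4 list had 3 rises (Herpud1, Sesn2 and Trib3) and 3 falls (Cdkn1a, Fgf21 and Sdf2l1) among 19. Cdkn1a, a cell cycle inhibitor gene, fell by 1.95 (SE 0.31) and Fgf21, a hormone gene and known PPARα target, fell by 1.37 (SE 0.31). NRF2 and oxidative stress genes had 3 rises (Ephx1, Gclm and Hmox1) and 1 fall (Gstm3) among 17, heat shock genes 1 fall (Hsp90aa1) among 10, and acute phase genes 1 rise (Il6ra) and 2 falls (Fgg and Lrg1) among 28. NF-kappaB and cytokine genes had 2 rises (Icam1 and Tnf) and 3 falls (Tnfaip2, Il1a and Il1b) among 24, the inflammatory cytokine gene Il1b being at -0.78 ± 0.13. Kupffer cell markers had 1 rise (Cd5l) among 16, and cholangiocyte markers 2 falls (Sox9 and Krt19) among 9. The 18 monocyte and neutrophil markers, 13 exocrine pancreas markers, 4 measured erythroid genes (of 13) and 30 oxidative phosphorylation genes had 0 calls by limma, over all genes or adjusted over the list alone, with 7 of these 65 genes at an unadjusted p under 0.05. The means per animal were 8.55 to 8.74 for oxidative phosphorylation. They were only 3.11 to 3.30 for pancreas, 3.79 to 3.95 for erythroid and 3.82 to 4.43 for monocyte and neutrophil genes. The array medians were 4.13 to 4.17, so 0 calls in those 3 dim lists say little about these cells.

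Nuclear receptors and their co-regulators changed in single members, 4 up (Nr1i3, Pparg, Ppargc1b and Nr1d1) and 4 down (Ppard, Hnf4g, Esr1 and Nrip1) among 27 (6 and 4 adjusted over the list alone), without a shift of the list. Ppard, which encodes the related receptor PPARδ, fell by 1.47 (SE 0.13), whereas Nr1i3, the gene of CAR, was up 0.75 (SE 0.071) and Pparg, the gene of PPARγ, up 0.70 (SE 0.11). Median, mean and test direction of a list differed in sign for 0 of the 20 shifted lists and for 9 of the other 23, whose medians lay within 0.061 of 0.

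With an estimated correlation camera called 0 of the 43 lists, 6 having an unadjusted p under 0.05 and the circadian clock the smallest adjusted p (0.0519), while fry called 18 lists one way and 38 in its mixed form. Camera with the preset correlation called a median of 6 lists in 99 other splits of the arrays and up to 17. A camera p as small was found only in the real split, 1 of 100, for 5 lists: textbook PPARA targets, peroxisomal genes, mitochondrial beta-oxidation, lipid droplets and the circadian clock. The mean of the members per animal overlapped between the genotypes for 11 of the 20 shifted lists. It did not for the other 9: PPARA targets, peroxisomal genes, mitochondrial beta-oxidation, omega-oxidation, lipid droplets, fatty acid uptake, the clock, female-biased genes and the cell cycle. Among the named genes, Cyp2c70, F5, Lpin2, Acadm, Lpl, Sox9, Cdh1, G6pc, Fbp1 and Col4a1 each lost the call in 10 or more of 21 alternatives, which include leaving out each single animal.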

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

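The tests of the clock arms, of the animals' sex, of the female-biased list, of the genes beside Ppara and of single lists over the splits were chosen only after the result was seen; the splits for the counts, and the relation of clock score and changed genes, were set before their results were seen. Chance is argued against for the number of changed genes: 1 of 100 drawn splits of the 12 arrays, the real one, gave as many as 2268, and the highest of the other splits gave 2. The same holds for genes changed at least 1.5-fold, with 1 of 100 splits, 508 genes against 1. The real split is always among the 100, so no smaller share was possible, and the other splits mix the genotypes. For the number of shifted lists 1 of 100 splits gave as many as 20, but the highest other gave 17. Of 99 other splits, 96 called at least 1 list. Of the 20 shifted lists, 13 had a camera p as small in 5 or more of the 100 splits, with counts of 5 for fatty acid uptake, thioesterases and female-biased genes, 7 for the cell cycle, 13 to 19 for interferon-stimulated genes, adipocyte markers, cholesterol synthesis, lymphocyte markers, xenobiotic metabolism, stellate cell genes and endothelial markers, and 22 and 23 for immediate early genes and fatty acid synthesis. The omega-oxidation and male-biased lists had 3.

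The clock score separated the genotypes without overlap. A lower drive by Arntl and Npas2 in Ppara KO was predicted to lower their 11 E-box target genes. Their median difference was 2.21, or 1.97 with the mean of transcript clusters, so the targets did not follow the lower mRNA of Arntl and Npas2 at collection. Each animal gave 1 time point and no protein was measured, so a lower drive over the day cannot be decided. Livers in different clock phases could account for the pattern: the E-box genes rose while the median of the BMAL1 side fell by 1.23, an arrangement of opposite phases that the daily cycle itself produces. A direct effect of the deletion on the clock cannot be told apart from a different time of collection or feeding, since the gap in clock score between the genotypes (2.47) lies between groups and the labels used here give no collection time. Whether clock phase also moved other genes stays open. The clock score was related to a score of the 2232 changed genes outside the clock and PPARA target lists, over 6 animals each and 4 relations computed. Genes that fell in Ppara KO entered that score with their sign turned. A positive correlation therefore means values further in the Ppara KO direction at a higher clock score. The 15 PPARA targets that fell were scored the same way, so a positive correlation there means lower mRNA at a higher clock score. Within Ppara KO Pearson r was 0.472 (exact permutation p = 0.342, adjusted 0.456) and Spearman rho 0.771 (exact permutation p = 0.103, adjusted 0.137), with r 0.884 without the 2 animals farthest from the median. Within WT Pearson r was -0.594 (exact permutation p = 0.208, adjusted 0.417) and Spearman rho -0.829 (exact permutation p = 0.0583, adjusted 0.137), with r -0.0603 without 2. With the 15 PPARA targets that fell the score correlated within Ppara KO at r = 0.704 (exact permutation p = 0.111, adjusted 0.417; Spearman rho 0.771, exact p = 0.103, adjusted 0.137; r 0.493 without 2) and within WT at r = -0.0933 (exact permutation p = 0.918, adjusted 0.918; Spearman rho -0.600, exact p = 0.242, adjusted 0.242; r -0.846 without 2), which leaves open as well whether these followed clock phase.

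In Ppara KO 10 of 23 female-biased genes fell and 4 rose, and 10 of 24 male-biased genes rose and 2 fell, with adjusted p = 0.334 and adjusted p = 0.300 for the lists with an estimated correlation. A male animal among the Ppara KO mice is argued against, since the highest mean of the Y-linked genes in Ppara KO minus that in WT was -0.0836 and Xist was at 10.03 or above in each Ppara KO liver, against 10.18 or above in WT. Of the 19 female-biased genes on no PPARA or fatty acid list 36.8% fell (7, with 3 rising and 9 not past the threshold). The 3 rises argue against a fall of the whole female programme. The 9 genes without a call do not show the absence of a change, so a broad but incomplete shift is not decided. Whether PPARA targets counted as female-biased genes are the whole cause stays open: the list of those 19 genes, with a median difference of -0.066, had a camera p of 0.0109, but p = 0.233 with an estimated correlation, a p as small in 21 of the 100 splits, and, with genes taken as independent, a 2-sided Fisher exact p of 5.69e-05 for its 7 falls against 5.74% of other genes. A shift in part of the sex-biased programme, through Ppara or clock phase, may remain and was not tested.

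Genes beside Ppara were called more often than the rest of its chromosome: 23 of the 100 nearest genes against 100 of 744 (2-sided Fisher exact p = 0.0153), by gene order in GRCm38.p6. Called shares were 16% before and 30% after Ppara. The 23 include Abcd2, 50 genes after Ppara, which was named above as a peroxisomal and female-biased fall. DNA of another strain kept around a targeted locus could do this, through probe mismatches or cis effects, as could neighbours that respond to PPARα. The wider window of 100 genes on each side, 38 of 200 against 85 of 644, had a 2-sided Fisher exact p of 0.0507, and genes that neighbour each other are not independent, so these cannot be told apart here.

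Single animals stood apart from their group in 21 of 372 values checked, which is close to the 18.6 that chance gives at about 1 in 20. Each is given as a log2 value with the range of the other 5 animals. Npas2 was 7.95 in WT animal 6, with the others between 7.60 and 7.70, and 4.63 in Ppara KO animal 5, with the others between 4.05 and 4.23. Dbp was 7.09 in WT animal 2 against 5.99 to 6.33, and the clock score of the same animal was -2.00 against -2.49 to -2.32. Lnx1 stood at 5.81 in Ppara KO animal 2, the others at 6.17 to 6.31. In WT animal 3, Acot7 was 6.15 against 6.33 to 6.42. Apom was 8.94 in WT animal 1, with 8.67 to 8.75 in the rest of its group. Bhmt stood at 5.02 in Ppara KO animal 1, the others at 4.54 to 4.62. In WT animal 4, C6 was 7.39 against 6.70 to 6.94. Cyp2c70 was 11.94 in WT animal 4, with 11.70 to 11.77 in the rest of its group. F5 stood at 10.77 in WT animal 1, the others at 10.88 to 10.94. In Ppara KO animal 3, Fabp4 was 6.82 against 5.52 to 5.91. Gstm3 was 7.71 in Ppara KO animal 2, with 8.32 to 8.57 in the rest of its group. H2-DMa stood at 4.62 in WT animal 2, the others at 4.92 to 5.00. Il1a stood at 6.42 in Ppara KO animal 4, the others at 6.05 to 6.18. In Ppara KO animal 1, Klrd1 was 3.39 against 3.90 to 4.16. Lpin2 was 8.52 in Ppara KO animal 4, with 9.20 to 9.40 in the rest of its group. Mir679 stood at 4.47 in Ppara KO animal 1, the others at 4.03 to 4.19. In WT animal 2, Phyh was 10.36 against 10.28 to 10.30. Plin2 was 10.46 in WT animal 1, with 9.71 to 9.91 in the rest of its group. Ppard stood at 5.71 in Ppara KO animal 5, the others at 6.00 to 6.16.

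Outside the named genes, 17824 transcript clusters without a single gene symbol were fitted on the same arrays, and 526 of them were called, 301 higher and 225 lower in Ppara KO. They stay unnamed here.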

How the results depend on the processing

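Leaving out the clock list, trimming the female-biased list and leaving out 3 WT animals were chosen only after the result was seen; the other alternatives were planned. Over the planned refits with another prior, weights, normalization, centring, dim-gene filter, cluster rule or feature set, the count of called genes stayed between 2168 and 2802 and that of genes changed at least 1.5-fold between 440 and 726. Stricter criteria lowered the counts by construction: 1070 genes at an adjusted p under 0.01, 329 with treat against 1.2-fold and 152 changed at least 2-fold. The number of shifted lists fell from 20 to 12 with genes at or above the median level, where the cause was not tested, and to 0 with an estimated correlation, which widens the test of lists whose members vary together. Leaving out 1 animal at a time gave 1817 to 2130 genes, 478 to 535 genes changed at least 1.5-fold, 18 to 21 lists and a Ppara difference of -0.022 to 0.072, the sign turning without WT animal 4. Same-numbered animals of the 2 genotypes did not deviate together over all genes (r -0.0471 to 0.0431, 1 of 12 arrays closest to its own number). No sign of pairing by number was seen, though an effect shared in few genes could be missed. With the replicate block 1672 genes, 505 genes changed at least 1.5-fold and 20 lists were called, and the Ppara difference was 0.032. Without WT 1, 3 and 5, high in adipocyte markers, 1008 genes, 479 changed at least 1.5-fold and 13 lists were called; over all 20 choices of 3 WT animals the counts were 846 to 1468 genes, as few in 7 choices, and 13 to 22 lists, as few in 1. Without the clock list 2245 and 492 genes were called, which cannot tell whether genes outside the list follow the clock. For named genes, 3576 values lay on the same side of the threshold, 267 lost and 4 gained a call, with 69 genes losing it at least once; Lpin2 turned to -0.0073 with the mean of clusters, since its clusters differ, and Fitm1 and Tef moved to -1.10 and 1.44 there. Across list results, 1040 of the values lay on the same side of the threshold, 58 lost and 17 gained a call. The lists were not run with an unmoderated model. Signal over background was not measured here, and the small differences of dim genes are the least certain.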

Other observations

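The following genes and groups were picked after their values were seen, and the test on the Dlk1 to Dio3 stretch was chosen only after the result was seen. Rian, a long noncoding RNA gene of the imprinted Dlk1 to Dio3 stretch, rose by 1.46 (SE 0.10, limma adjusted p 3.46e-07), like the small nucleolar RNA genes AF357425 and AF357355, which lie within it in GRCm38.p6 and whose signal was not separated here from that of the host transcript. Of 55 genes measured between Dlk1 and Dio3, 10 rose and 0 fell. Without Rian, AF357425 and AF357355, which drew attention to the stretch, 7 of 52 rose, where 4.46% of all genes did (2-sided Fisher exact p = 0.00785, genes there not being independent). Among the other rises were the microRNA genes Mir382 (0.43 ± 0.085) and Mir679 (0.46 ± 0.10).

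In the antigen presentation list, which was not called (camera adjusted p 0.130), 4 class II genes rose: H2-Aa by 0.55 (SE 0.14), H2-Ab1 by 0.55 (SE 0.12), H2-Eb1 by 0.48 (SE 0.10) and H2-DMb1 by 0.45 (SE 0.11), 4 of 13 members with 0 falls, and 4 and 0 adjusted over the list alone. Further class II genes of the list, H2-DMa at 0.12 ± 0.089 and the transactivator gene Ciita at 0.26 ± 0.13, were not called, nor were B2m, a class I component gene, at 0.067 ± 0.053 and H2-K1 at 0.056 ± 0.065.

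Pnpla3, a lipase gene of the fatty acid and triglyceride synthesis list, fell by 1.80 (SE 0.39) and Cyb5r3, a cytochrome b5 reductase gene, by 1.00 (SE 0.056), both on the chromosome of Ppara, 26 and 41 genes before it in the gene order of GRCm38.p6.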
